A study of Mus musculus with 6 samples.

How the data were processed

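Total RNA of 6 mice was labelled with biotin and hybridised to Illumina mouse bead arrays, per the labels, with 3 mice in the WT vehicle group and 3 in the KO tamoxifen group. Groups and replicate numbers were taken from the sample titles, which call the arrays biological replicates. The deposited raw table holds, per the file headers, an intensity for each of 45281 probes on each array and a detection p-value beside it. The deposited intensities show no sign of normalization between arrays, since their medians differ from 121.8 to 132.4, and no background was subtracted, since the lowest signals are 89.7 to 95.1. The scanner software and bead summary are not given in the sources used here. The deposited detection p-values were taken to be the share of negative control beads at least as bright as the probe. A deposited log2 table of the same arrays was compared with the raw table. It equals the log2 raw signals after quantile normalization within 5e-05, with array medians of 7.01, so its scale and direction are settled and its genes are not centred. All columns with values per sample were used, and 0 were left aside.

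The raw intensities were normalized with limma 3.58.1 in R 4.3.3, by neqc. This corrects the background by a normal plus exponential model whose negative controls are inferred from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. Inferred controls stand in for measured control beads. Folds of dim genes depend on the background correction and the offset. Probes were kept if detected at p under 0.05 on at least 3 of the 6 arrays, which left 19082. Gene names came from the platform annotation, which gives 1 symbol for 34885 probes, several for 18 and none for 10378, and 34807 Entrez identifiers matched a RefSeq gene table of assembly GRCm38.p6, used for names and for the order of genes beside Myc only. Kept probes without a single symbol number 2807, of which 299 were higher and 420 lower in KO when tested alone. Each gene was represented by its probe with the highest mean over all arrays, which gave 10209 genes. Of the called genes, 1496 have further kept probes, and for 20 of these a further probe was called in the other direction. Further probes of some named genes moved the same way but did not pass when tested among all kept probes. Among them, with the log2 fold change, were those of Gata1 (0.46), Fas (0.23), Pgk1 (-0.36), Cyrib (-0.26), St3gal1 (0.44) and Mxd1 (0.49).

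Each gene was tested on the log2 scale with lmFit and eBayes, 2-sided, for KO tamoxifen minus WT vehicle with group as the only term, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Errors of fold changes are standard errors of that fit. A gene not detected on any array of a group has only a bound there. Its fold was computed against the higher, per array, of its own signal and the lowest signal detected on that array. The genes named were chosen by a rule: Myc, Pvt1 and the neighbours of Myc past the test, the 12 largest rises and 12 largest falls among called genes with symbols whose groups do not overlap, and up to 4 called members of each list with the largest change, or, where none passed, up to 3 with the smallest p. A few further genes were named outside this rule, as said where they are given. Immunoglobulin, histone, MHC and T cell receptor genes are uncertain where near-identical copies can share a probe. Lists of 38 pathways, cell types and gene groups were written from textbook knowledge. Of the lists, 36 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The groups, the tests of genes and lists, the lists, the rule and the alternatives were fixed before the data were examined. The set of genes nearest to Myc, the symbol families and most tests of explanations were chosen later, as said where they are given. The alternatives were other background corrections, scaling to a common median, the deposited log2 table, other filters on dim probes, the mean of a gene's probes, the replicate number as a block, trend and robust eBayes, array weights, a 2-fold minimum, and leaving out each array in turn.

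The fit was tested on simulated data with 200 changed genes among 10209. It recovered 5.97% of 67 genes at a log2 change of 0.5, 59.7% of 67 at 1 and 96.97% of 66 at 2, with 6 false calls. Small changes were thus often missed in the simulation. With the 3763 genes called in the data the adjusted threshold is less strict, so these shares need not hold for the data. The list test called a list shifted by a log2 change of -0.5 and 0 of the 34 lists sharing no gene with it. The simulated genes were drawn independently, whereas the estimated correlation within the lists in the data was up to 0.53, for erythroid genes. The simulation therefore cannot show how often lists of correlated genes are falsely called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.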

Results

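RNA from 6 mice of the C57 BL6 strain was measured on Illumina bead arrays, 1 array per mouse. The series concerns an enhancer of the proto-oncogene Myc, called N-Me, which the transcription factor NOTCH1 binds. The labels place 3 mice in a wild-type group (WT) given corn oil alone and 3 in a knockout group (KO) given tamoxifen at 3 mg/kg by intraperitoneal injection, and the animals were processed 40 h later. Tamoxifen is commonly used to switch on a recombinase that deletes a marked DNA segment. Genotype and treatment changed together, so each difference below is between WT mice given vehicle and KO mice given tamoxifen. The labels name no tissue. Each array held 45281 probes, of which 18215 to 19486 were detected at p under 0.05, and the median raw signal was 121.8 to 132.4. Over the 10209 genes tested, arrays correlated at r of 0.990 to 0.993 within WT, 0.984 to 0.991 within KO and 0.950 to 0.969 between groups. These correlations are across genes, which are not independent replicates. The small number of arrays limits the precision.

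The first question was whether Myc transcript differed between the WT vehicle and KO tamoxifen groups. Myc was 3.37-fold lower in KO, at a normalized log2 signal of 8.91 ± 0.15 (SD, n = 3) in WT and 7.16 ± 0.24 (SD, n = 3) in KO. The log2 fold change was -1.75 ± 0.16 (SE), with an adjusted p of 0.000406 by limma. The WT arrays read 8.95, 8.75 and 9.04 and the KO arrays 7.42, 6.95 and 7.11. The exact permutation test over the assignments of 3 against 3, 2-sided, gave p = 0.1, the smallest it allows. A further Myc probe was not detected on any array. The array measures the Myc transcript, not the enhancer, so it does not show the deletion itself.

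Genes beside Myc on the chromosome moved in both directions. Of 23 tested neighbours fixed as a list, 5 fell and 2 rose, and these counts were also 5 and 2 adjusted over the list alone. Over all 10209 tested genes 1748 fell and 2015 rose. The share of neighbours that fell was near that over all genes, and the share that rose was below it. The list median was -0.16 (camera, adjusted p = 0.109, but 0.00323 by fry). The neighbours that fell were Ndrg1, a stress-responsive gene, at -1.70 ± 0.14 (SE), Cyrib at -0.60 ± 0.14, Sqle, an enzyme of cholesterol synthesis, at -0.50 ± 0.12, Washc5 at -0.50 ± 0.16 and Nsmce2 at -0.48 ± 0.12. St3gal1, a sialyltransferase, rose by 0.87 ± 0.20 and Tmem65 by 0.38 ± 0.12. Pvt1, the non-coding gene next to Myc, was at -0.28 ± 0.21 (adjusted p = 0.323), but at -0.07 without WT replicate 2 and -0.43 without WT replicate 3. Of the 20 tested genes nearest to Myc, a set chosen after the data were seen, 5 fell and 1 rose. The falls there were Sqle, Washc5, Nsmce2, Cyrib and Tg, the thyroglobulin gene, at -0.95 ± 0.16 (adjusted p = 0.00303), and the rise was Tmem65. With single arrays left out, Tmem65 lost its call in each of the 6 cases (adjusted p up to 0.113), and also when scaled to the same median or with a replicate block. Washc5 lost it without WT replicate 1, WT replicate 3 or KO replicate 3 (up to 0.125). It also lost it with either other background correction (down to -0.24), with the deposited log2 table, when scaled to the same median, with no filter on dim probes and with trend and robust eBayes (0.0539 to 0.0748). The call of Nsmce2 was lost without WT replicate 1, WT replicate 3 or KO replicate 2 (up to 0.0605).

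Across all tested genes, 2015 were higher and 1748 lower in KO at an adjusted p under 0.05, and 499 of these were higher and 323 lower by at least 2-fold. Counts of called list members are to be read against the 2015 and 1748 of all 10209 genes tested. Quantile normalization gives all arrays the same distribution, so higher and lower are relative to it. The largest falls were in Car12, a membrane carbonic anhydrase, at -4.30 ± 0.19 (SE, log2 fold change), and Bcat1, an aminotransferase of branched-chain amino acids, at -3.95 ± 0.12. Next came Ctla4, an inhibitory receptor of T cells, at -3.10 ± 0.39, and Shmt1, a serine hydroxymethyltransferase of folate metabolism, at -2.92 ± 0.12. They were followed by H2-T18 at -2.91 ± 0.19, Esm1 at -2.86 ± 0.34, and Rag1, which cuts antigen receptor genes for recombination, at -2.80 ± 0.20. Sertad4 was at -2.69 ± 0.18, Alpl at -2.61 ± 0.36, Ccdc169 at -2.61 ± 0.28, the tight-junction gene Cldn4 at -2.55 ± 0.22 and Upk1b at -2.41 ± 0.23. Car12, Bcat1 and Ctla4 were detected on only 2 of the 3 KO arrays, and the size and order of such falls depend on the background correction. Without it Car12 was at -2.61, Shmt1 at -2.47, Bcat1 at -2.38 and Ctla4 at -1.72. With the correction, a further Car12 probe also passed, but at -2.47, and a further Shmt1 probe at -2.79. The size and rank of the Car12 fall thus also depend on the probe.

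Among the largest rises, Chac1, which degrades glutathione, was not detected on any WT array and was at least 6.04-fold higher in KO (adjusted p = 0.00229). Nkg7, a gene of cytotoxic granules, rose by 2.89 ± 0.19 (SE), and the interferon-induced genes Usp18, Isg15, Irf7 and Ifit3 by 2.55 ± 0.20, 2.48 ± 0.24, 2.22 ± 0.13 and 2.19 ± 0.17. The chemokine genes Ccl21a and Ccl21c rose by 2.57 ± 0.56 and 2.21 ± 0.49, and these near-identical copies can share a probe, as can copies of the MHC gene H2-T18 above. The remaining rises of this size were in Fn3k at 2.52 ± 0.40, Dleu2 at 2.36 ± 0.19 and Lgi1 at 2.29 ± 0.20. Further probes of these genes passed at smaller rises for Ifit3 (0.86), Fn3k (1.26), Usp18 (1.87) and Lgi1 (1.67 and 2.08). A further Ccl21c probe was at 2.49. The chemokine gene Cxcl10 was not detected on any WT array and was at least 2.92-fold higher in KO (adjusted p = 0.000309). These bounds hold for the background correction used, and without it Chac1 was at 1.49 and Cxcl10 at 0.92. KO and WT arrays did not overlap for 5152 genes, 50.5% of those tested against 10% by chance. Without WT replicate 3 the counts were 1342 higher and 1144 lower, and without WT replicate 1 the count of lower genes was 1143. Another 115 called genes have clone or predicted names and are only counted.

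**Figure D1:**
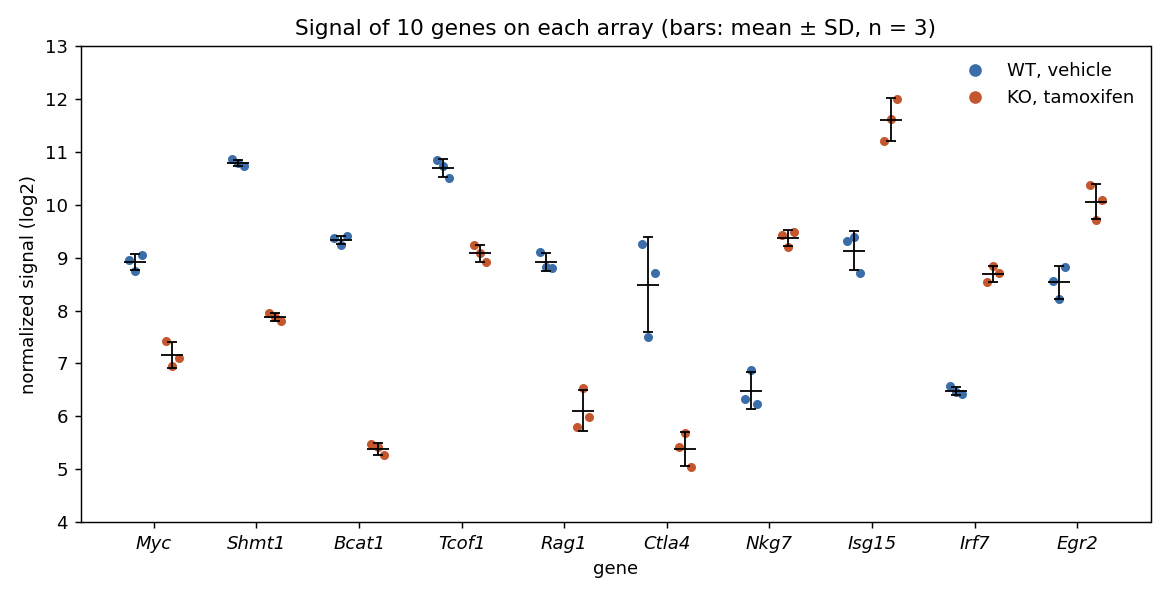
Normalized log2 signal (vertical axis) of 10 genes on each of the 6 arrays, with WT vehicle in blue, KO tamoxifen in orange, and bars for the mean ± SD of 3 arrays. Myc lies at 8.75 to 9.04 in WT and 6.95 to 7.42 in KO. The groups do not overlap for any of the 10 genes. Most of these were drawn from the largest rises and falls, for which the rule required this.

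The genes of cell growth fell together. Of 54 tested growth genes known as MYC targets, 43 fell and 2 rose (46 and 2 adjusted over the list alone). The median log2 fold change was -0.66 (bootstrap 95% interval over genes -0.76 to -0.57; camera, adjusted p = 1.85e-13; adjusted p = 0.105 with an estimated correlation). The falls were led by Tcof1, a cofactor of ribosomal RNA synthesis, at -1.61 ± 0.14 (SE), the DNA repair genes Apex1 at -1.11 ± 0.20 and Ung at -1.10 ± 0.12, and Wdr43 at -1.11 ± 0.18. The 2 that rose, named after their values were seen, were the transferrin receptor gene Tfrc at 1.08 ± 0.19 and Odc1, the first enzyme of polyamine synthesis, at 0.42 ± 0.13. Odc1 lost its call without WT replicate 1, WT replicate 3, KO replicate 2 or KO replicate 3 and when scaled to the same median (adjusted p up to 0.139). Of 79 ribosome biogenesis genes, 63 fell and 0 rose (66 and 0 adjusted over the list alone), and all 79 had negative values. The median of the ribosome biogenesis genes was -0.74 (interval -0.83 to -0.58; camera, adjusted p = 2.75e-19; adjusted p = 0.128 with an estimated correlation). Nsun2, an RNA methyltransferase, was at -2.04 ± 0.28, Tsr1 at -1.60 ± 0.21 and Rrp1b at -1.47 ± 0.16. A further probe of Tsr1 was higher in KO, at 0.65. The lists share 16 genes.

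Genes of ribosomal proteins, the mitochondrial ribosome and translation factors were counted next. Of 50 ribosomal protein genes, 4 fell and 0 rose (also 4 and 0 adjusted over the list alone), at a median of -0.11 (camera, adjusted p = 0.0944). The 4 were Rps15a at -1.35 ± 0.18 (SE), Rplp0 at -0.94 ± 0.14, Rpl22 at -0.52 ± 0.12 and Rpl4 at -0.47 ± 0.11. Rpl22 lost its call without WT replicate 1 (adjusted p = 0.0504). The list passed the test when arrays were scaled to the same median (median -0.27, adjusted p = 0.000767), with no filter on dim probes (0.0171), with the mean of a gene's probes (0.0333) and by fry (0.00641). Its median was -0.06 without WT replicate 2. Among 69 genes of the mitochondrial ribosome, 24 fell and 3 rose (28 and 3 adjusted over the list alone), at a median of -0.24 (camera, adjusted p = 0.000429; adjusted p = 0.284 with an estimated correlation). Examples were Mrps6 at -0.86 ± 0.15, Mrps35 at -0.85 ± 0.12, Mrps27 at -0.81 ± 0.18 and Mrps15 at -0.73 ± 0.22. Mrps15 lost its call in 5 of the 6 cases with an array left out, all but KO replicate 2 (adjusted p up to 0.0884). Of 39 translation factors and tRNA synthetases, 15 fell and 3 rose (16 and 3 adjusted over the list alone), at a median of -0.28 (camera, adjusted p = 0.00103; adjusted p = 0.278 with an estimated correlation). The initiation factor genes Eif1a at -1.30 ± 0.14, Eif2s2 at -0.89 ± 0.14, Eif4e at -0.84 ± 0.17 and Eif3b at -0.64 ± 0.14 were among them.

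Several biosynthetic pathways were lower in KO. Of 30 genes of nucleotide synthesis, 19 fell and 2 rose (20 and 2 adjusted over the list alone), at a median of -0.55 (camera, adjusted p = 9.06e-06; adjusted p = 0.105 with an estimated correlation). Besides Shmt1, the purine enzyme gene Atic was at -1.02 ± 0.14 (SE), Dut, which removes dUTP, at -1.01 ± 0.20 and the pyrimidine enzyme gene Cad at -0.96 ± 0.15. Of 18 genes of cholesterol synthesis, 7 fell and 0 rose (9 and 0 adjusted over the list alone), at a median of -0.35 (camera, adjusted p = 0.00285; adjusted p = 0.237 with an estimated correlation). They included Hsd17b7 at -1.24 ± 0.15, Cyp51 at -0.93 ± 0.13, Insig1, a regulator of the pathway, at -0.80 ± 0.26 and Msmo1 at -0.77 ± 0.15. Insig1 lost its call without WT replicate 1 (adjusted p = 0.128) or WT replicate 3 and was at -0.48 without KO replicate 1. Of 15 glycolysis genes, 7 fell and 2 rose (also 7 and 2 adjusted over the list alone), at a median of -0.34 (camera, adjusted p = 0.0305; adjusted p = 0.237 with an estimated correlation). Pgk1 was at -0.98 ± 0.14, Pdk1, which restrains pyruvate oxidation, at -0.85 ± 0.16, Pkm at -0.75 ± 0.12 and Pfkm, a phosphofructokinase, at 0.82 ± 0.12. The glycolysis list lost its call without WT replicate 2 (adjusted p = 0.0514) or KO replicate 2 (0.0530).

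Of 67 genes of oxidative phosphorylation, 9 fell and 0 rose (2 and 0 adjusted over the list alone), at a median of -0.09 (camera, adjusted p = 0.0697). Subunit genes with the largest falls were Atp5k at -1.74 ± 0.23 (SE), Sdhd at -1.08 ± 0.30, Cox7b at -0.85 ± 0.22 and Atp5e at -0.73 ± 0.18. Sdhd and Atp5e lost their calls without WT replicate 1 or KO replicate 3, and Cox7b without WT replicate 1 or WT replicate 3 (adjusted p up to 0.0713). The list passed without WT replicate 3 (0.0146) or KO replicate 3 (0.0325), when arrays were scaled to the same median (median -0.24, 0.00135), with no filter on dim probes (0.0183), with the mean of a gene's probes (0.0210) and with trend and robust eBayes (0.0486). Without WT replicate 2 the median was -0.05, and the adjusted p was up to 0.186 with single arrays left out.

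**Figure D2:**
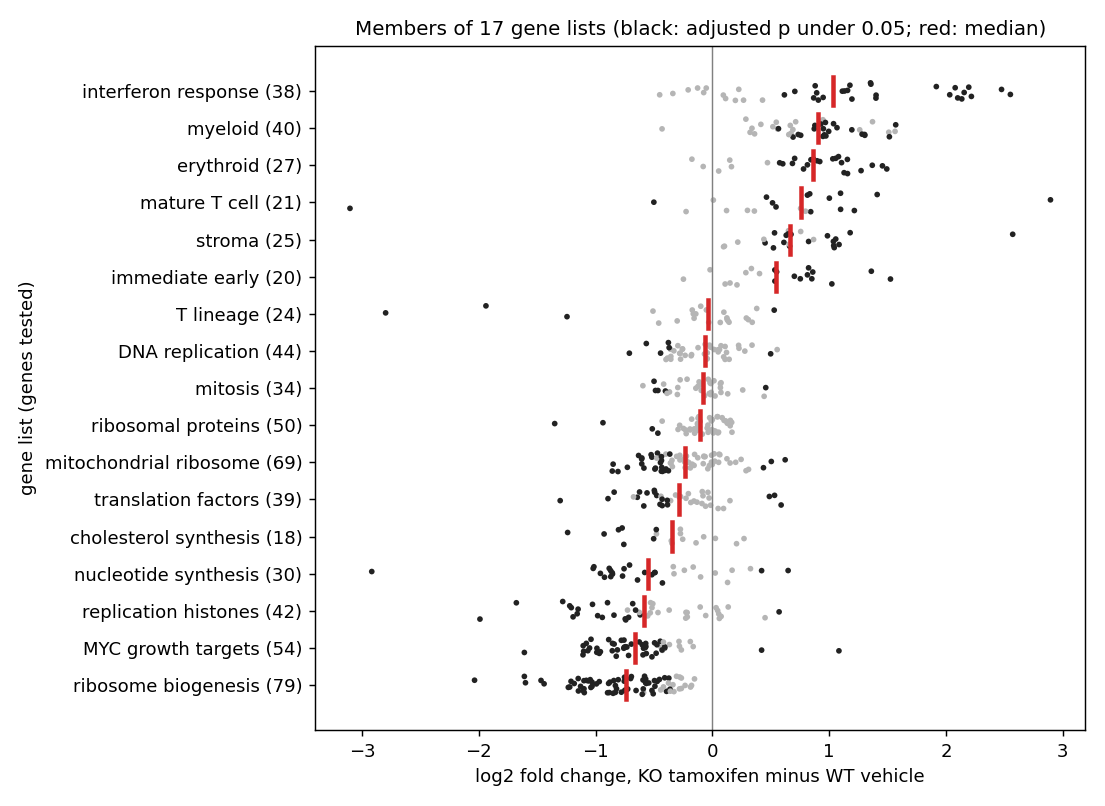
Log2 fold change (horizontal axis, KO tamoxifen minus WT vehicle) of each tested member of 17 gene lists, black where the adjusted p is under 0.05, with the list median in red. The medians run from -0.74 for ribosome biogenesis to 1.03 for interferon response genes.

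Few genes of the cell cycle passed the test. Of 44 DNA replication genes, 5 fell and 1 rose (0 and 0 adjusted over the list alone), at a median of -0.07 (camera, adjusted p = 0.171). The polymerase genes Pole and Pold1 were at -0.71 ± 0.18 (SE) and -0.57 ± 0.14, the helicase gene Mcm6 at -0.44 ± 0.14 and the cyclin gene Ccne2 at 0.50 ± 0.15. Of 34 mitosis genes, 4 fell and 1 rose (0 and 0 adjusted over the list alone), at a median of -0.08 (camera, adjusted p = 0.171). The spindle and cytokinesis genes Bub1b, Kif20b and Aurkb were at -0.50 ± 0.13, -0.49 ± 0.16 and -0.47 ± 0.13, and the phosphatase gene Cdc25b at 0.46 ± 0.15. Of these 8 genes, Pold1 alone kept its call with each array left out. Pole lost it without WT replicate 3 (adjusted p = 0.0534) and Bub1b without WT replicate 3 or KO replicate 3. Aurkb lost it without any 1 WT array or KO replicate 1, and Kif20b in all cases but KO replicate 2. Cdc25b lost it in all cases but KO replicate 1, Mcm6 in all but WT replicate 1 and KO replicate 2, and Ccne2 without any 1 WT array or KO replicate 3 (adjusted p up to 0.157). Both lists passed when arrays were scaled to the same median (-0.19, adjusted p = 0.0281, and -0.16, 0.0400). Without KO replicate 2 the medians were -0.11 for replication and -0.14 for mitosis, and without WT replicate 2 the mitosis median was -0.04.

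Among replication histone genes, more fell than rose, and 22 did not pass the test. Of 42 tested, 19 fell and 1 rose (21 and 1 adjusted over the list alone), at a median of -0.59 (camera, adjusted p = 9.06e-06; adjusted p = 0.320 with an estimated correlation). H3c3 was at -1.99 ± 0.27 (SE), H2ac4 at -1.68 ± 0.18, H3c1 at -1.28 ± 0.20 and H3c7 at -1.22 ± 0.17. Histone genes are near-identical copies that can share a probe, so these names are uncertain, and a further H3c7 probe was at 0.09. H3c7 lost its call with the mean of its probes (adjusted p = 0.0665). Without KO replicate 1 the list median was -0.39.

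Genes of quiescence and differentiation rose, with exceptions. Of 29 listed genes, 16 rose and 3 fell (17 and 3 adjusted over the list alone), at a median of 0.43 (camera, adjusted p = 0.00166; adjusted p = 0.229 with an estimated correlation). The transcription factor genes Klf6 and Foxo3 were at 1.02 ± 0.22 (SE) and 0.97 ± 0.21 and Gadd45a at 0.92 ± 0.17, while Ndrg1 fell, as given among the neighbours of Myc. Of 24 p53 target genes, 5 rose and 2 fell (also 5 and 2 adjusted over the list alone), at a median of 0.00083 that was negative under several alternatives (camera, adjusted p = 0.843). The largest changes after Gadd45a were in Zmat3 at -0.82 ± 0.12, the repair gene Ddb2 at -0.64 ± 0.11 and the death receptor gene Fas at 0.60 ± 0.14. Of 24 genes of the BCL2 family and apoptosis, 9 rose and 1 fell (10 and 1 adjusted over the list alone), at a median of 0.27 (camera, adjusted p = 0.0643). Bid was at -1.19 ± 0.16, while Bok rose by 1.03 ± 0.17, Cflar by 0.94 ± 0.15 and Bmf by 0.77 ± 0.21. Bmf lost its call without WT replicate 3 or KO replicate 3 (adjusted p up to 0.0803), and the list passed without KO replicate 1 (0.0474), with no filter on dim probes (0.0114) and by fry (0.0162).

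Interferon response genes showed the largest list median of the rises. Of 38 tested, 26 rose and 0 fell (27 and 2 adjusted over the list alone), at a median of 1.03 (bootstrap 95% interval over genes 0.66 to 1.35; camera, adjusted p = 6.90e-10; adjusted p = 0.229 with an estimated correlation). Usp18, Isg15, Irf7 and Ifit3 rose as given above, by 4.58-fold to 5.86-fold for the brightest probe of each. Further probes of Usp18 and Ifit3 rose less, as also given there. The list mean lay above that of WT on each KO array, by 0.93, 1.15 and 1.00. Immediate early genes also rose, 12 of 20 with 0 falling (also 12 and 0 adjusted over the list alone), at a median of 0.54 (camera, adjusted p = 0.000161; adjusted p = 0.274 with an estimated correlation). Egr2 and Egr3, transcription factors induced by T cell receptor signalling, were at 1.52 ± 0.21 (SE) and 1.36 ± 0.17, and Ppp1r15a at 0.86 ± 0.22. Ppp1r15a lost its call without WT replicate 1 (adjusted p = 0.0653) or WT replicate 3 (0.0555). Of 24 genes of T cell activation, 11 rose and 2 fell (11 and 3 adjusted over the list alone), at a median of 0.49 (camera, adjusted p = 0.00173; adjusted p = 0.229 with an estimated correlation). Bcl3, a regulator of NF-kappaB, rose 2.84-fold (log2 SE 0.16), while Ctla4 fell. Of 36 lysosome and autophagy genes, 17 rose and 1 fell (19 and 3 adjusted over the list alone), at a median of 0.44 (camera, adjusted p = 0.00714; adjusted p = 0.237 with an estimated correlation). Gabarapl1 and Wipi1 of autophagosome formation were at 1.03 ± 0.18 and 0.99 ± 0.20, and the lysosomal genes Grn and Ctsh at 0.96 ± 0.14 and 0.95 ± 0.17. Markers of erythroid, myeloid and stroma cells, given below, rose on the same KO arrays. Whether the rises of quiescence, immediate early, T cell activation and lysosome genes, and of mature T cell genes below, follow from these was not tested.

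T cell genes moved in both directions. Of 24 T lineage genes, 3 fell and 1 rose (also 3 and 1 adjusted over the list alone), at a median of -0.04 (camera, adjusted p = 0.382, but 0.0380 by fry) that was -0.01 without WT replicate 1 and -0.09 without KO replicate 2. The 3 that fell were Rag1, the pre-T receptor gene Ptcra at -1.94 ± 0.20 (SE) and Dntt at -1.25 ± 0.18, and Themis rose by 0.53 ± 0.12. Of 21 genes of immature double-negative thymocytes, 8 rose and 6 fell (9 and 8 adjusted over the list alone; camera, adjusted p = 0.780), with the receptor gene Kit at 1.33 ± 0.25. Their median was 0.13, and -0.0073 when arrays were scaled to the same median. Of 18 genes of double-positive thymocytes, 4 rose and 8 fell (7 and 8 adjusted over the list alone; camera, adjusted p = 0.298, but 0.0149 by fry), at a median of -0.05 that was 0.0019 without KO replicate 2. Ets2 was at -1.24 ± 0.15 and Arpp21 at -0.92 ± 0.15, with a further Arpp21 probe at 0.05. Of 21 mature T cell genes, 12 rose and 2 fell (also 12 and 2 adjusted over the list alone), at a median of 0.75 (camera, adjusted p = 0.000452; adjusted p = 0.128 with an estimated correlation). After Nkg7, the homing receptor gene Itgb7 rose by 1.41 ± 0.12 and Cd52 by 1.22 ± 0.21, while Ctla4 fell. Of 18 NOTCH target genes, 5 fell and 3 rose (also 5 and 3 adjusted over the list alone), at a median of -0.19 that was -0.12 without KO replicate 3 (camera, adjusted p = 0.155). Ptcra, the repressor gene Hes5 at -1.29 ± 0.24 and Igf1r at -0.94 ± 0.15 fell, and Hey1 rose by 0.79 ± 0.15. A further Igf1r probe was at 0.21.

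Markers of other blood and tissue cells rose in KO. Of 27 erythroid genes, 21 rose and 0 fell (also 21 and 0 adjusted over the list alone), at a median of 0.87 (camera, adjusted p = 1.31e-07; adjusted p = 0.320 with an estimated correlation). Icam4 was at 1.49 ± 0.23 (SE), Dmtn at 1.46 ± 0.24, the transcription factor gene Gata1 at 1.37 ± 0.19 and Kel at 1.27 ± 0.22. A further Gata1 probe was at 0.46 and did not pass. Of 40 myeloid genes, 21 rose and 0 fell (also 21 and 0 adjusted over the list alone), at a median of 0.90 (camera, adjusted p = 1.31e-07; adjusted p = 0.320 with an estimated correlation). The macrophage genes Aif1, C1qa and Cx3cr1 were at 1.57 ± 0.18, 1.30 ± 0.20 and 1.30 ± 0.22, with Cx3cr1 detected on 2 of the 3 WT arrays, and Siglec1, not detected in WT, was at least 2.11-fold higher (adjusted p = 0.00193; 0.58 without background correction). Of 25 genes of stroma, endothelium and epithelium, 17 rose and 0 fell (18 and 0 adjusted over the list alone), at a median of 0.66 (camera, adjusted p = 1.99e-06; adjusted p = 0.284 with an estimated correlation). Besides Ccl21a, the chemokine gene Cxcl12 was at 1.18 ± 0.20 and the matrix genes Col1a1 and Sparc at 1.08 ± 0.31 and 1.06 ± 0.19. Col1a1 lost its call without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 3 (adjusted p up to 0.0861).

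Some B cell and platelet genes rose past the test, in shares near that over all genes tested, of which 2015 of 10209 rose. Most members had positive values, 15 of 16 B cell genes and 13 of 14 platelet genes. Of 16 B cell genes, 3 rose and 0 fell (also 3 and 0 adjusted over the list alone), at a median of 0.67 (camera, adjusted p = 0.0106; adjusted p = 0.424 with an estimated correlation). Cd22 was at 1.93 ± 0.19 (SE) and Xbp1, a factor of plasma cells and protein secretion, at 0.71 ± 0.14. Fcer2a, not detected in WT, was higher in KO (adjusted p = 0.0271), but at 0.34 and past no threshold without background correction (0.0576), and at 0.57 without KO replicate 2. The B cell list lost its call without KO replicate 2 (median 0.30, adjusted p = 0.0759), and its median was 1.01 without KO replicate 1. It also lost its call with the stricter filter on dim probes (0.0796) and by fry (0.0762). Of 14 platelet and megakaryocyte genes, 3 rose and 1 fell (also 3 and 1 adjusted over the list alone), at a median of 0.65 (camera, adjusted p = 0.0268; adjusted p = 0.472 with an estimated correlation). Vwf was at 1.11 ± 0.14, Gp9 at 1.08 ± 0.30, Clec1b at 0.62 ± 0.15 and P2rx1 at -1.96 ± 0.22. The platelet list lost its call without KO replicate 2 (adjusted p = 0.0992) or KO replicate 3 (0.0623) and by fry (0.123), and its median was 1.04 without KO replicate 1. Of 5 NK cell genes, 4 of them also on the mature T cell list, 2 rose, Nkg7 and Il2rb at 0.83 ± 0.23 (also 2 adjusted over the list alone; camera, adjusted p = 0.116, but 0.0417 with the mean of a gene's probes and 0.00323 by fry). The NK cell median was 0.75, and 0.31 without KO replicate 2. Il2rb was at 0.55 without WT replicate 1. Fcer2a lost its call without any 1 WT array or KO replicate 3, Gp9 without WT replicate 1, WT replicate 3, KO replicate 2 or KO replicate 3, and Il2rb without WT replicate 3 or KO replicate 3 (adjusted p up to 0.0828). None of the 15 listed hepatocyte and adipocyte genes was among those tested. Of the sex-linked genes, Xist read 9.97 to 10.9 and Uty 5.20 to 5.78 on the 6 arrays, with no difference past the test (adjusted p = 0.409 and 0.238).

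**Figure D3:**
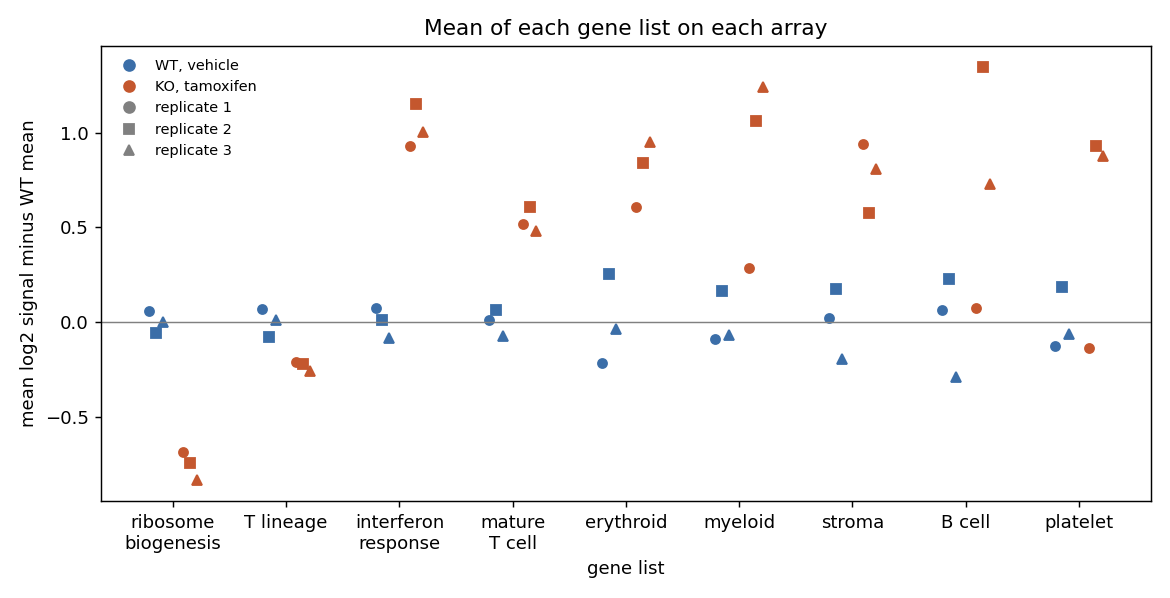
Mean log2 signal of 9 gene lists on each array minus the WT mean (vertical axis), with WT vehicle in blue, KO tamoxifen in orange and a marker shape for each replicate number. Ribosome biogenesis lies at -0.84 to -0.68 on the KO arrays, and KO replicate 1 lies at 0.07 for B cell and -0.14 for platelet genes.

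Over the 36 lists with at least 5 tested genes, camera with a preset correlation called 11 higher and 8 lower. With an estimated correlation camera called 0, with 7 at an unadjusted p under 0.05, and fry, which asks whether a list moves on balance one way without comparing it with other genes, called 26. Other splits of the same 6 arrays gave 8 to 17 called lists by the preset test. Each of them mixes WT and KO arrays on both sides and keeps part of the group difference, so these counts are not rates of false calls.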

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

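No array was left out or setting added after the data were seen. Myc stayed lower in KO and past the threshold under every alternative run, from -1.25 without background correction to -1.88 without KO replicate 1 (adjusted p up to 0.00463). With a 2-fold minimum, 499 genes were higher and 323 lower. Leaving out single arrays gave 1342 to 2092 higher and 1143 to 1837 lower genes, with fewer arrays per fit. The lowest counts came without WT replicate 3 for higher genes (1342) and without WT replicate 1 or 3 for lower genes (1143 and 1144). The median of the MYC growth targets was -0.70 to -0.62 with single arrays left out. Its camera call was lost with an estimated correlation (median -0.66, adjusted p = 0.105), and the number of called lists was then 0, with 7 at an unadjusted p under 0.05 and 26 by fry. Camera with an estimated correlation allows for correlation among a list's genes. Correlation alone does not account for the lost calls. Called lists with an estimated correlation below the preset 0.01 lost theirs too, namely nucleotide synthesis (-0.017), glycolysis (-0.026) and mature T cell genes (-0.0082). The number of called lists was 17 to 25 under the other alternatives run. With the replicate number as a block, 2016 genes were higher and 1697 lower and 19 lists were called. Same-numbered WT and KO arrays correlated at 0.17, 0.12 and -0.08 in their deviations from the group means, and not every array correlated best with its own number, so the numbers were not taken to pair the mice. A block for the slide was not run, because slides are not given in the sources used here. The deposited log2 table and the raw signals without background correction gave nearly the same values, since one is the normalized form of the other.

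The median of the p53 targets, 0.00083 and past no threshold, turned to -0.0056 with normexp at an offset of 50, -0.0074 without background correction and with the deposited log2 table, -0.053 when scaled to the same median, -0.048 with the mean of probes and -0.076 with array weights. It was -0.069 to 0.14 with single arrays left out. The median of double-negative thymocyte genes turned to -0.0073 when scaled to the same median, and that of double-positive thymocyte genes was -0.16 to 0.0019 with single arrays left out. The cause of these turns was not tested. Over the other comparisons of named genes with an alternative, 2225 kept direction and call, 114 lost the call and 0 changed sign, and a gene that a stricter filter removed has no value there. With no filter on dim probes, which tests more genes, Mrps15, Sdhd, Insig1, Ccne2, Kif20b, Cdc25b, Fcer2a, Il2rb, Gp9 and Col1a1 also lost their calls. So did Ccne2 and Cdc25b when scaled to the same median, Cdc25b with the mean of probes, Insig1 with a replicate block, Mcm6 and Kif20b with array weights, and Fcer2a without background correction or with the deposited log2 table. Over those of lists, 561 kept both, 26 lost the call and 31 gained it. Of the probes, 40.2% to 43.0% were detected over background on an array, and genes near background have compressed folds.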

Other observations

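All tests of explanations in this part were chosen after the result was seen, except the count of interferon genes above other cells' markers and the splits of the arrays. Of 29 genes of the unfolded protein and ATF4 response, 9 rose and 3 fell (11 and 3 adjusted over the list alone), at a median of 0.23 (camera, adjusted p = 0.0846, but 0.0263 without KO replicate 1, 0.0493 with no filter on dim probes and 0.0458 with array weights). Besides Chac1, the stress factor gene Ddit3 was at 1.39 ± 0.20 (SE) and the asparagine synthetase gene Asns at 1.18 ± 0.18, whereas Phgdh, the first enzyme of serine synthesis, was at -1.98 ± 0.15. Of 24 heat shock and chaperone genes, 4 rose and 5 fell (4 and 7 adjusted over the list alone), at a median of -0.26 (camera, adjusted p = 0.0846, but 0.0492 without KO replicate 2 and 0.0316 to 0.0466 when scaled to the same median, with either other filter or by fry). Hspa4l was at 1.34 ± 0.22, Hsph1 at 0.93 ± 0.16, Hspa4 at -0.81 ± 0.17 and Cacybp at -0.58 ± 0.13. Of 28 proteasome genes, 2 fell and 0 rose (0 and 0 adjusted over the list alone), at a median of -0.12 (camera, adjusted p = 0.154, but 0.0146 when scaled to the same median and 0.0454 by fry), namely Psmb1 at -0.88 ± 0.23 and Psmd2 at -0.42 ± 0.14. Psmb1 lost its call without WT replicate 1, WT replicate 3 or KO replicate 3, and Psmd2 in all cases but WT replicate 3 and KO replicate 2 (adjusted p up to 0.127). Psmd2 also lost it with either other background correction (down to -0.21), with the deposited log2 table, when scaled to the same median, with the mean of probes (-0.28) and with trend and robust eBayes (0.0697 to 0.116).

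Among 11 tested partners and relatives of MYC, Mxd1, an antagonist of MYC, rose by 0.85 ± 0.18 (SE) and no other passed (also 1 adjusted over the list alone), at a median of 0.22 that was 0.04 without KO replicate 3 (camera, adjusted p = 0.293). Of 11 estrogen receptor targets, 3 rose and 1 fell (also 3 and 1 adjusted over the list alone), at a median of 0.36 (camera, adjusted p = 0.171, but 0.0137 by fry). Igfbp4 was at 1.39 ± 0.18, Igf1 at 1.03 ± 0.16, Xbp1 at 0.71 ± 0.14 and the cyclin gene Ccnd1 at -0.76 ± 0.15. In a test of 252 families of genes that share the start of their symbol, chosen after the data were seen, the Rrp (median -0.81), Exosc (-0.59), Utp (-0.85), Polr (-0.32) and Gtf (-0.35) families of RNA processing and synthesis and the Eif (-0.28) and Mrps (-0.36) families of translation were lower. The collagen family Col (0.76, 10 rose and 1 fell) and the antiviral Oas family (1.43, 4 rose and 0 fell) were higher (camera, adjusted p = 0.0200 to 0.0414; adjusted p = 0.791 with an estimated correlation).

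The fall of MYC growth targets and ribosome biogenesis genes was weighed against 5 explanations. A lower share of T lineage cells would lower T lineage genes as far, but their median lay 0.70 above that of ribosome biogenesis (bootstrap 95% interval over genes, which are not independent, 0.46 to 0.90). This speaks to the lineage as a whole only. Genes of different T cell stages moved in both directions, as given above, and a shift between stages was not tested. Fewer dividing cells would lower mitosis genes as far, but their median lay 0.66 above that of ribosome biogenesis (0.46 to 0.79). Of the other corrections and scalings, the weakest left a ribosome biogenesis median of -0.55 against -0.74. Each of them, like the main processing, sets the arrays to a common distribution or median. They therefore cannot show a change shared by most genes. Fewer cells in S phase cannot be told apart, because the median of replication histones lay 0.15 above that of ribosome biogenesis (-0.09 to 0.33), which goes with it, and that of DNA replication genes 0.68 above (0.40 to 0.79), which does not. A response of these genes to lower Myc may account for the pattern, as a hypothesis, but tamoxifen or the recombinase itself cannot be told apart from the deletion, because 0 of the WT arrays came from mice given tamoxifen.

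The rise of erythroid, myeloid and stroma markers was weighed against a lower share of the main cell type, which would raise all other types alike. The labels do not name the main cell type, so that these are markers of other cells is an assumption. Over the means of the KO arrays, the medians of these and of B cell and platelet markers spread over 0.25 (permutation p against shuffled list labels = 0.541), but that averages over arrays that moved apart. Array by array, in a test added after that one, the spreads were 1.05, 1.08 and 0.53 in KO (sum 2.67). They were 0.52, 0.26 and 0.54 for each WT array against the other 2 (sum 1.33). The permutation p was 0.0001 for both sums, the smallest the draws can give. With 2 of 3 KO arrays wider than each WT array, a lower share cannot be told apart from other changes. The rule for this reading was revised more than once after the values were seen. A single KO array is not the source, since the myeloid median was still 0.72 without the array whose loss lowered it most (0.90 with all). Some bright genes are given here outside the rule for named genes. The erythroid Hba-a1 was at 0.16 ± 0.11 (SE, adjusted p = 0.283 by limma) and did not pass the test. Nor did Slc4a1 at -0.18 ± 0.15 (adjusted p = 0.379 by limma), which was at -0.05 without KO replicate 2 and -0.29 without KO replicate 1. Of the 27 erythroid genes, 21 rose, as given above. The myeloid Lyz2 was at 1.19 ± 0.22. A change in the number or state of single cell types stays open, untested.

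The rise of interferon genes was weighed against more cells of other types and a single array. Of the 38 interferon genes, 14 rose above 1.30, the level that 10% of the pooled erythroid, myeloid, stroma, B cell and platelet markers pass (exact binomial p = 9.34e-06, 1-sided; genes are not independent). By chance 10% would pass, so interferon genes passed that level more often than the pooled markers. Under the other corrections and scalings, a check chosen later, 9 to 13 passed (exact binomial p up to 0.0111). The count cannot decide on more cells of these 5 types, because whether the markers rise as far as the share of such cells was not tested. Markers near background have compressed folds, and markers that the main cells also express would rise less. More cells of these types therefore stay open as a cause. Without any 1 KO array the median was at least 0.96, against 1.03 with all. An interferon response in KO may account for the pattern, as a hypothesis, but tamoxifen or the recombinase itself cannot be told apart from the deletion, with 0 WT arrays given tamoxifen.

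Splits of 3 arrays against 3 number 10, too few for a share under 0.05. Every split but the real one mixes WT and KO arrays on both sides. It keeps part of the group difference and puts the rest into the spread within its sides. Low counts of called genes in such splits are therefore largely set in advance, and the splits cannot decide on chance. In each of the 4 results, 1 split, the real one, was as large. The real split gave 2015 higher and 1748 lower genes and the highest other 0, with 70 to 662 genes at an unadjusted p under 0.05 by limma against 4782. For the called lists these values were 19 and 17, and for the size of the MYC growth target median 0.66 and 0.28.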
